A study of Mus musculus with 6 samples.

How the data were processed

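RNA was extracted with an RNeasy kit and libraries were made with a SMARTer mRNA-seq kit, per the labels' protocols. The submitters' processing notes name the mouse genome builds GRCm38 and mm10. This conflicts with the rows of the deposited table, all 20323 of which are human Ensembl genes with human descriptions, so that 0 row identifiers match the mouse annotation. The aligner, the counting tool, the annotation release and whether counting used strand are not given in the sources used here. No human annotation was used, so genes are named as the table names them, with no coordinates or GC content, and gene length was taken only as counts over FPKM, for a check in the closing section.

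The deposited table gives, per the file headers, a raw count and an FPKM value per gene and library. It also holds the authors' mean FPKM per group (with 0 written as 0.001), their log2 ratio of these means, and their p-value and adjusted p per gene. The authors' log2 column differs from the log2 ratio of their mean FPKM columns by at most 7.11e-15 in any row. Their adjusted p differs from a Benjamini-Hochberg adjustment over the 15691 rows with a count by at most 2.89e-15, and the test behind their p-value is not stated in the sources used here. Samples were grouped by the treatment in the labels. Titles of the CXCL10 samples carry a volume of 5 µl, whose concentration is not given. Nothing in the labels says that replicates came from separate cultures, so the spread that p-values measure may be technical. In the unpaired fit this is the spread between libraries of a group. In the fit paired by replicate number it is only the spread of the differences between same-numbered libraries.

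Counts per library ranged from 12838106 to 15587409, so that 3 counts, the limit a count of 0 allows, equal 0.192 to 0.234 CPM. This covers counting error only. No 2 libraries of a group agreed within sampling noise: the chi-square statistic per degree of freedom was 3.07 and 2.79 between replicates 2 and 3 of the groups, 16.2 and 17.4 between TGF-β replicate 1 and the others, and 8.44 and 8.81 between CXCL10 replicate 1 and the others.

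Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, Benjamini-Hochberg threshold of 0.05), which kept 11970 genes. Log2 CPM values use a prior count of 2. The test without a replicate block was fixed before the data were examined as the principal one, with the block as an alternative. Both are given because the replicate numbers met the rule of the following check. The deviations of same-numbered libraries from their group means correlated across genes at 0.330, 0.121 and 0.163, each over 0.1, and each library correlated best with its own number. Over genes with a mean of at least 5 CPM the same-number values were 0.536, 0.228 and 0.202, while the crossed values between replicates 2 and 3 were 0.262 and 0.237. At those genes the numbers thus did not pair replicates 2 and 3. The pairing comes from the data, not from the labels. Standard errors and adjusted p values of the paired fit are conditional on this pairing, which was taken from the same counts. Since deviations sum to 0 within a group, a large deviation of replicate 1 makes replicates 2 and 3 deviate together, so the check rests mainly on replicate 1 of both groups against the rest. The rule of 0.1 was fixed beforehand, but the correlations and the number of calls in each fit were first seen together.

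Gene lists (33, with 679 genes, fixed before the data were examined) were written as mouse symbols and matched to human symbols, and 667 genes had a row. The 28 lists with at least 5 tested members were compared with the other genes by camera in limma 3.58.1 with a preset correlation of 0.01. They were tested again with an estimated correlation and with fry, which asks whether a list's genes move one way without comparing them with other genes. Of the 11 lists past the threshold without the block, 0 passed with an estimated correlation or with fry, and of the 8 with the block 0 passed with an estimated correlation and 8 lists passed with fry. These were 5 of the camera lists together with the type I interferon, G2/M and pericyte lists. GO and KEGG terms of the deposited table with 15 to 300 tested genes were treated in the same way. Genes named in the text are the 12 with the largest change in each direction among genes past the threshold, with a mean of at least 5 CPM and groups that do not overlap, up to 4 members per list with the lowest p, and 11 genes fixed by name. Some genes that this rule names are not reported here. The first part of the rule gave 0 genes without the block and was applied to the paired fit once this had been seen. Of the annotation terms, the 5 with the lowest p in each direction were named where they passed the threshold. Standard errors, fold changes and adjusted p values in the text are those of the paired fit unless another is named, and means ± SD are TMM-scaled CPM over 3 libraries.

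The procedure was tested on simulated counts with the real means and library sizes, 200 changed genes among 11851 without the block and 11846 with it. At 1.5-fold it recovered 60% without and 74% with the block, at 2-fold 86% and 90%, and at 4-fold and 8-fold 100% in both, with 8 and 4 unchanged genes called. Simulated genes varied independently of each other. The run without the block held no shift of replicate 1 shared across genes, and the run with the block took the pairing as given. These rates therefore do not give the power of either fit on the real libraries. Alternatives were RLE scaling, library totals alone, DESeq2 1.42.0, limma-voom, no filter, a stricter filter, an adjusted p of 0.01, the block, leaving out each library, and limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 1. Figures were drawn with matplotlib 3.10.9.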

Results

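The series holds 6 RNA-seq libraries from a kidney fibroblast line that the labels call RFB. In 3 libraries the cells had received TGF-β, the cytokine used to drive fibroblasts toward a fibrotic state, and in 3 they had received TGF-β together with CXCL10, a chemokine that signals through the receptor CXCR3. The labels call the organism mouse, yet all 20323 gene rows carry human Ensembl identifiers and human gene names, so every level given here is a level on a human gene model. The 3 TGF-β libraries held 14266272, 15587409 and 13068015 counts and the 3 CXCL10 libraries 14470051, 12838106 and 13547550, with a count on 13939 to 14224 genes in each. The series description speaks of a SUV39H1 knockdown, while the sample labels name these treatments and no knockdown, and the groups here follow the labels. Between 4.04% and 4.50% of counts lay on mitochondrially encoded genes.

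The comparison addresses what CXCL10 does to the expression of TGF-β-treated fibroblasts. With CXCL10 the cells had higher levels of ANGPTL4, EDN1, IL11, PTGS2 and ITGA2. Gene lists of cholesterol synthesis, of endoplasmic reticulum and cytosolic chaperones and of glycolysis were shifted upward, and lists of the amino acid stress response, p53 targets and antioxidant genes downward, by a test that presets the correlation between genes (camera). With an estimated correlation 0 of the lists passed (smallest adjusted p = 0.497), and of the p53 and antioxidant lists fewer genes fell than were left uncalled. Most changes were small, with a median of 0.33 (log2) among the genes that rose and -0.38 among those that fell. All of these gene calls rest on a fit that pairs libraries by replicate number, which called 1162 genes higher and 962 lower of 11970 tested at an adjusted p under 0.05 (edgeR quasi-likelihood). With the same pairing DESeq2 called 684 and 454, and limma-trend on log2(FPKM + 1) 369 and 397. Of the edgeR calls, 87 were higher and 66 lower by at least 2-fold. Separate paired fits gave, at that size, 53 and 19 with a mean of at least 5 CPM and 34 and 13 by limma-trend. They gave 140 and 116 without both libraries of replicate 1 and 55 and 40 without those of replicate 3. Without both libraries of replicate 2 the paired calls numbered 680 and 561, and without those of replicate 3 539 and 365. Without the pairing, edgeR called 0 genes, with a smallest adjusted p of 0.161, although 2449 genes had an unadjusted p under 0.05. At the same threshold without pairing, limma-voom called 0 and DESeq2 called 172 higher and 163 lower, all of them among the paired calls in the same direction. By the adjusted p of the authors' deposited table, 112 genes were higher and 97 lower at that threshold, and 110 and 95 of them were paired calls. Scaling by library totals alone turned the split of paired calls to 877 higher and 1359 lower.

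Replicate 1 of both groups stood apart along the axis that parted the treatments. The first principal component held 48.4% of the variance, and TGF-β replicate 1 scored 5.54 on it, against -28.3 and -29.5 for the other TGF-β libraries and 9.78 and 9.67 for CXCL10 replicates 2 and 3. CXCL10 replicate 1 lay farthest out, at 32.8. By distance over all tested genes, TGF-β replicate 1 was nearer to each CXCL10 library, at 39.7 to 45.8, than to its own group, at 48.7 and 49.5. With TGF-β replicate 1 left out and no pairing, edgeR called 1302 genes higher and 1046 lower, and 1035 and 815 of them were paired calls. Leaving out any other single library gave 0 calls.

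**Figure D1:**
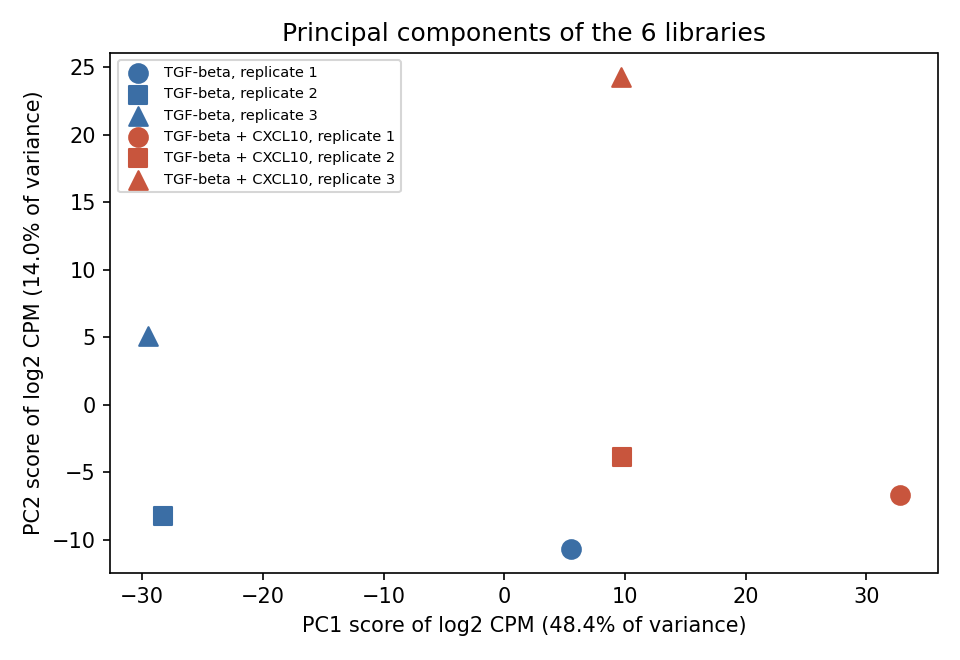
Scores of the 6 libraries on the first 2 principal components of log2 CPM (arbitrary units, 48.4% of variance on the first). Colours mark the treatment and shapes the replicate number; TGF-β replicate 1 lies at 5.54 on the first component, between the other TGF-β libraries at -28.3 and -29.5 and the CXCL10 libraries at 9.67 to 32.8.

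Among genes with at least 5 CPM whose groups did not overlap, the largest rise was that of ANGPTL4 (ENSG00000167772), a secreted inhibitor of lipoprotein lipase, from 3.59 ± 2.56 CPM to 14.4 ± 9.18 CPM (SD, n = 3 per group), a paired log2 change of 2.01 (SE 0.17, adjusted p = 9.85e-06). OASL (ENSG00000135114), an interferon-induced antiviral gene, also rose by 2.01 (SE 0.31), from 2.38 ± 2.21 CPM to 8.51 ± 1.82 CPM. EDN1 (ENSG00000078401), which encodes the vasoconstrictor endothelin-1, rose by 1.63 (SE 0.24). IL11 (ENSG00000095752), a cytokine induced by TGF-β in fibroblasts, rose by 1.32 (SE 0.09), and PTGS2 (ENSG00000073756), the inducible cyclooxygenase, by 1.39 (SE 0.11). The collagen receptor subunit ITGA2 rose by 1.53 (SE 0.14). TMEM158, PDE4B, IL7R, PODXL and TNFSF15 rose by 1.31 to 1.75. For every gene of this paragraph TGF-β replicate 1 was the highest of the TGF-β libraries. It held 465 CPM of ITGA2, 246 of PODXL, 25.7 of IL7R and 56.6 of IL11. The lowest CXCL10 libraries held 469, 247, 26.2 and 57.4 CPM, and TGF-β replicate 2 held 133, 72.5, 7.78 and 20.6 CPM. The relative gap to the lowest CXCL10 library was wider for the other genes. Being chosen from genes whose groups did not overlap, all genes of this paragraph had to be higher in each of the 3 pairs. None of them passed the unpaired test, where their adjusted p values lay between 0.161 and 0.182.

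The genes that fell most included BMF (ENSG00000104081), a pro-apoptotic BCL2-family gene, from 42.4 ± 16.9 CPM to 16.8 ± 5.33 CPM (paired log2 change -1.31, SE 0.10, adjusted p = 6.51e-06). DEPTOR (ENSG00000155792), an inhibitor of the mTOR kinase, changed by -1.15 (SE 0.12), from 22.7 ± 4.12 CPM to 10.3 ± 2.51 CPM. PTGES (ENSG00000148344), a prostaglandin E synthase, changed by -1.07 (SE 0.09) while PTGS2, which makes its substrate, rose. The adhesion receptor ADGRG1 changed by -1.02, and IP6K3, MLC1, KLHL24, KCNH2 and SEMA6D by -1.22 to -1.01. TMEM119 fell from 65.1 ± 21.5 CPM to 32.0 ± 6.91 CPM. The T cell costimulatory ligand ICOSLG has a pair of rows under one symbol, with changes of -1.48 and -1.25, and its reads could be shared between them. DESeq2 without pairing also called all of these genes except BMF (adjusted p = 0.0728) and TMEM119 (0.0712), with adjusted p values from 0.000113 to 0.0375. Of the genes with the largest rises named here it called EDN1 (0.000978) and PDE4B (0.0180). For every gene of this paragraph that fell, TGF-β replicate 1 was the lowest of the TGF-β libraries. It held 23.0 CPM of BMF, 27.0 of PTGES, 10.1 of KLHL24 and 10.2 of KCNH2. CXCL10 replicate 2 held 20.9, 24.6, 9.88 and 10.1 CPM, and TGF-β replicate 2 held 51.6, 50.4, 19.2 and 16.9 CPM. The gap was wider for DEPTOR, at 18.5 CPM against at most 11.8. In the unpaired edgeR test each gene that fell had an adjusted p of 0.161.

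**Figure D2:**
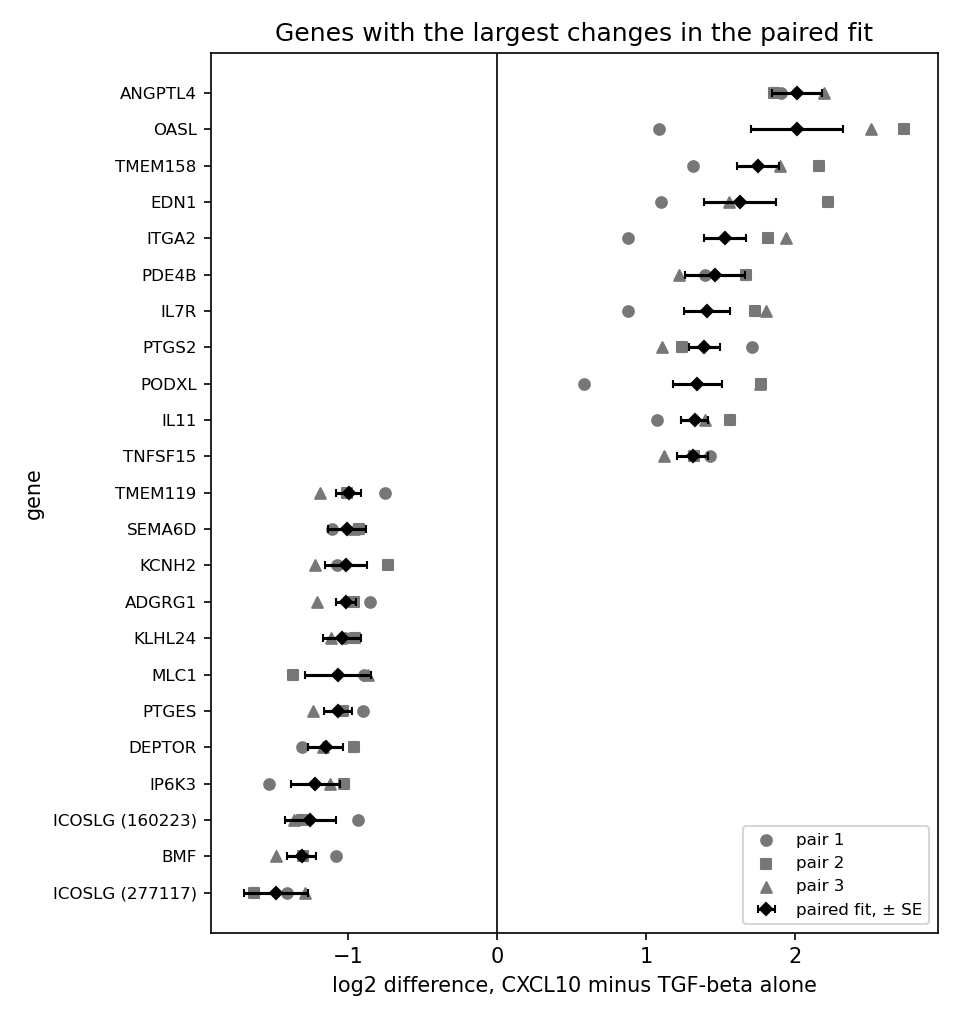
Log2 difference between the CXCL10 and TGF-β library of each pair (grey, one shape per pair) and the paired fit with its standard error (black) for the genes with the largest rises and falls that are reported here. All 3 pairs lie on the same side of 0 for each row, which the choice of genes with non-overlapping groups requires. ANGPTL4 reached 2.01 and ICOSLG -1.48.

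Transcripts of the ligand and its receptor were at or near the limit of detection at this depth. CXCR3 had 0 counts in all 6 libraries, which allows up to 0.192 to 0.234 CPM per library for counting error only, and CXCL10 itself had 4 counts in one CXCL10 library and 0 in the other 5. SUV39H1, the H3K9 methyltransferase named in the study's title, stood at 4.77 ± 0.95 CPM and 6.09 ± 0.90 CPM, with a paired log2 difference of 0.36 (SE 0.21, adjusted p = 0.283). Of 20 H3K9 methylation and heterochromatin genes, 2 rose and 6 fell in the paired fit, or 3 and 7 adjusted over the list alone. Its paralog SUV39H2 fell (-0.91, SE 0.25), as did CBX5 (-0.23), which encodes a heterochromatin protein, while UHRF1 (0.52) and TRIM28 (0.24) rose. The list as a whole did not pass (camera adjusted p = 0.359 unpaired and 0.312 paired), and its median in replicate 1 differed from that in replicates 2 and 3 by -0.11. On the CXCR3 axis, with 4 genes tested, ACKR3 fell by 0.98 on the log2 scale (adjusted p = 9.87e-06) and DPP4, the protease that truncates CXCL10, changed by -0.16 (adjusted p = 0.0280), both also when adjusted over the list alone, while SDC4 (0.04) and SDC1 (0.06) passed no test.

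Fibrosis genes did not move as one. ACTA2 (ENSG00000107796), the smooth muscle actin that marks myofibroblasts, fell in the paired fit from 1151 ± 153 CPM to 865 ± 180 CPM (log2 change -0.43, SE 0.05, adjusted p = 8.60e-05; 0.184 unpaired). TAGLN differed by 0.00 (SE 0.05). COL1A1 fell slightly (-0.14, SE 0.03, adjusted p = 0.00835), and COL3A1 at -0.11 did not pass (adjusted p = 0.0532). The groups overlapped for ACTA2 and COL1A1. In scaled CPM, TGF-β replicate 1 lay below CXCL10 replicate 2 for both genes, and for COL1A1 also below CXCL10 replicate 3. FN1 rose by 0.21 (SE 0.04), CCN2, a matricellular TGF-β target, by 0.82 (SE 0.09), and TGFB1 by 0.36 (SE 0.06). None of these passed the unpaired test. Among 28 tested matrix genes 6 rose and 1 fell in the paired fit (6 and 2 adjusted over the list alone), with THBS1 at 0.70, COL6A3 at 0.19 and COL4A1 at 0.12. Of 21 contractile genes 5 rose and 6 fell (6 and 6 adjusted over the list alone), with LMOD1 (-1.03) and DES (-0.78) lower and SMTN (0.66) and ACTN1 (0.22) higher. Neither list passed (camera adjusted p = 0.359 and 0.902 unpaired, 0.441 and 0.497 paired).

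The TGF-β immediate targets passed without the pairing (camera adjusted p = 0.0483), and not with it (0.0887) or with an estimated correlation (adjusted p = 0.497). The call was also lost without TGF-β replicate 1 (adjusted p = 0.0597) or 2 (0.0744) and without CXCL10 replicate 2 (0.0588) or 3 (0.136). The list median changed little, from 0.11 in both fits to between 0.10 and 0.14 in these leave-outs. Of their 20 members 6 rose and 2 fell in the paired fit, or 10 and 2 adjusted over the list alone. The risers included IL11 and the sphingosine kinase SPHK1 (0.60), and the transcriptional corepressor TGIF1 (-0.46) fell. Of 22 YAP/TAZ targets 5 rose and 2 fell (7 and 2 adjusted over the list alone), with CCN1 (0.47), F3 (0.45) and FJX1 (1.05) higher and AJUBA (-0.49) lower, and the list did not pass (adjusted p = 0.104 unpaired and 0.124 paired). Of 22 matrix proteases and inhibitors 8 rose and 2 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.273 unpaired and 0.213 paired), among them PLAU (0.87), ADAM19 (0.92) and TIMP3 (0.31) upward and MMP11 (-0.59) downward. Among 10 BMP targets GREM1, a BMP antagonist, rose (1.22) and BAMBI, a decoy receptor, fell (-0.77), or 1 and 2 adjusted over the list alone, and the list gave an adjusted p of 0.427 unpaired and 0.314 paired.

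Most cholesterol synthesis genes rose. In the paired fit 19 of 23 rose and 2 fell (20 and 2 adjusted over the list alone), with IDI1 and MVD, enzymes of the mevalonate pathway, at 0.42 (SE 0.05) and 0.44 (SE 0.07). SREBF2, the transcription factor that drives these genes, was one of those that fell (-0.17, a gene named after its value was seen, as are those called so below). The list passed with camera in both fits (adjusted p = 6.66e-06 unpaired and 4.29e-06 paired) and with fry in the paired fit only (0.0333), and not with an estimated correlation (adjusted p = 0.497). Its median was 0.17 higher in replicate 1 than in replicates 2 and 3 of the same group. Within the TGF-β group alone this difference was 0.21, beside a paired treatment median of 0.25.

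Many chaperones of the endoplasmic reticulum and the cytosol were higher as well. Of 19 unfolded protein response genes 12 rose and 0 fell in the paired fit (15 and 0 adjusted over the list alone), including EDEM1 (0.35), HYOU1 (0.33), MANF (0.40) and PDIA4 (0.29). Of 15 cytosolic heat shock genes 9 rose and 1 fell (9 and 1 adjusted over the list alone), with HSPA8 at 0.71, HSP90AB1 at 0.46 and STIP1 at 0.36, and the small heat shock protein HSPB1 at -0.58. Glycolysis and hypoxia genes gave 11 risers and 1 faller of 23 (14 and 1 adjusted over the list alone), with changes of 0.20 for GAPDH, 0.26 for PGK1 and PKM and 0.22 for the lactate exporter SLC16A3. These lists passed in both fits, with paired camera adjusted p values of 3.13e-05, 0.00504 and 0.00157, and none did with an estimated correlation (paired adjusted p = 0.497 in each). With fry in the paired fit glycolysis passed (0.0333), and the chaperone lists did not (0.0785 and 0.0869). Their medians were 0.23, 0.24 and 0.11 higher in replicate 1 than in replicates 2 and 3. Within the TGF-β group alone these differences were 0.25, 0.25 and 0.14, beside paired treatment medians of 0.26, 0.23 and 0.15. The shift of TGF-β replicate 1 was thus about as large as the change with CXCL10.

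Many genes of the integrated stress response and amino acid synthesis were lower. In the paired fit 14 of 21 fell and 0 rose (17 and 0 adjusted over the list alone), including NUPR1 (-0.67), SESN2 (-0.55), CTH (-0.42) and PHGDH (-0.31), the first enzyme of serine synthesis. DDIT3, which encodes CHOP, was at -0.78 and ATF4 at -0.22, both named after their values were seen. Of 20 p53 targets 8 fell and 1 rose (8 and 2 adjusted over the list alone), with the pro-apoptotic BBC3 at -0.82, the antiproliferative BTG2 at -0.87, TP53INP1 at -0.76 and CCNG1 at -0.32. Of 18 NRF2 antioxidant genes 6 fell and 0 rose (7 and 0 adjusted over the list alone), among them the ferritin chains FTL (-0.26) and FTH1 (-0.28), GSR (-0.32) and TXNRD1 (-0.28). All 3 lists passed in both fits, with paired camera adjusted p values of 4.70e-06, 0.00486 and 0.00739, and none with an estimated correlation (paired adjusted p = 0.497 in each). With fry in the paired fit the stress response and antioxidant lists passed (0.0333 in each), and the p53 targets did not (0.0785). Their medians in replicate 1 differed from those in replicates 2 and 3 by -0.29, -0.11 and -0.08. Within the TGF-β group alone these differences were -0.20, -0.23 and -0.07, beside paired treatment medians of -0.24, -0.17 and -0.19. For the stress response and p53 lists the shift of replicate 1 was thus about as large as the change with CXCL10.

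**Figure D3:**
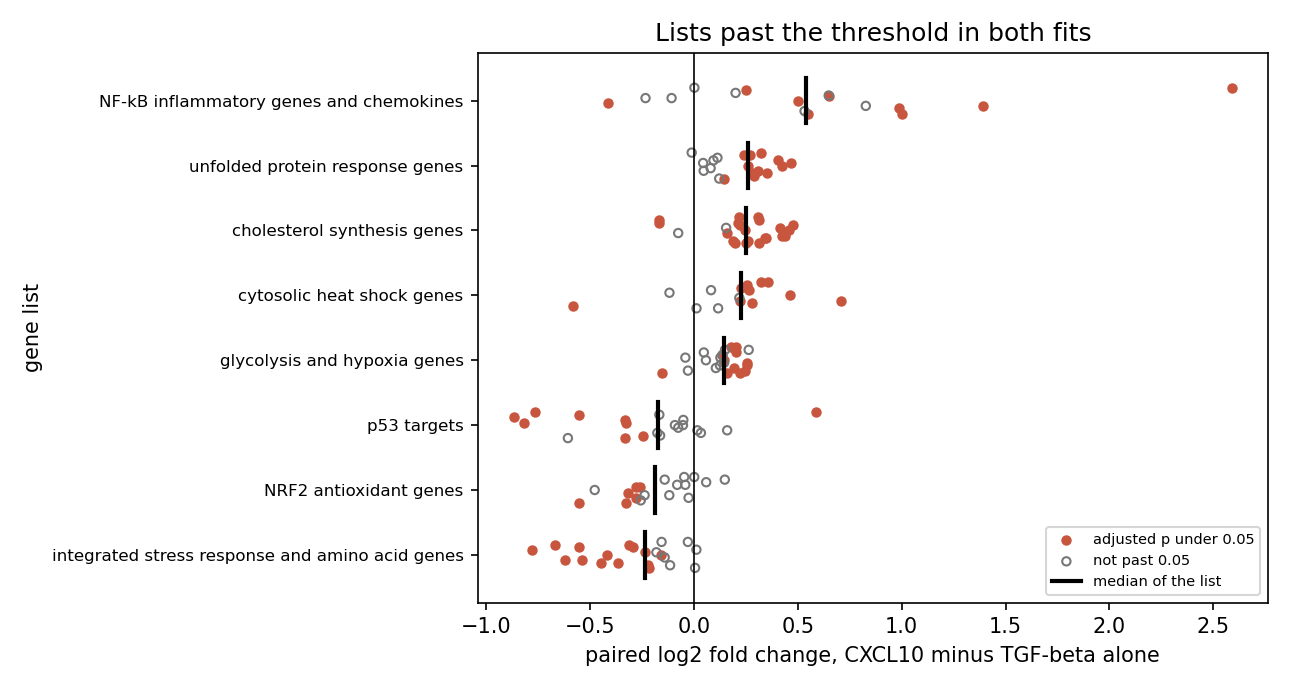
Paired log2 fold change (x axis) of each tested member of the 8 gene lists past the camera threshold in both fits, filled where the gene's adjusted p was under 0.05, with the list's median as a black bar. Medians ran from -0.24 for the integrated stress response to 0.54 for the NF-κB list.

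Part of the NF-κB list was higher, while interferon genes went both ways. Of 16 NF-κB genes 8 rose, 1 fell and 7 were not called in the paired fit (10 and 2 adjusted over the list alone), with the NF-κB cofactor NFKBIZ at 0.99 (SE 0.15), PTGS2 at 1.39, the cytokine LIF at 0.65 and NFKB2 at 0.50. The list passed in both fits (camera adjusted p = 0.00381 unpaired and 0.00173 paired; fry 0.00980 paired), and not with an estimated correlation (adjusted p = 0.497), and its median was 0.36 higher in replicate 1. Within the TGF-β group alone this difference was 0.34, beside a paired treatment median of 0.54. Of 22 type I interferon-stimulated genes 7 rose and 6 fell (9 and 6 adjusted over the list alone). IFI44 rose by 2.04, OASL by 2.01 and IFIT3 by 1.04, while PARP14 fell by 0.55 (log2). The level of IFI44 was low, at 1.47 ± 1.23 CPM and 5.52 ± 0.73 CPM, and its 3 pairs differed by 1.09, 2.61 and 2.49. The interferon list did not pass camera (adjusted p = 0.359 unpaired and 0.213 paired) but passed fry in the paired fit (0.000371), with a median 0.12 higher in replicate 1. Of 18 interferon-γ and antigen presentation genes 2 rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.273 unpaired and 0.306 paired): CD274, which encodes PD-L1 (0.92), and GBP3 (0.34) upward, and IRF1 (-0.61) and PSMB8 (-0.43) downward.

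Few proliferation genes passed the test. Among 22 S phase genes 1 fell (TYMS, -0.41) and 0 rose, and 0 passed adjusted over the list alone, and among 19 G2/M genes 0 passed either way. Their medians were 0.09 and 0.30, with camera adjusted p values of 0.435 and 0.0762 unpaired and 0.306 and 0.124 paired, and the G2/M list passed fry in the paired fit (0.00472). Of 22 immediate early genes 6 rose and 4 fell (6 and 4 adjusted over the list alone), with FOSL1 (0.71), MYC (0.63) and DUSP1 (0.35) higher and BTG2 (-0.87) lower. The list had a median of 0.05 beside a mean of -0.05 in the unpaired fit (camera adjusted p = 0.590 unpaired and 0.731 paired). Nuclear oxidative phosphorylation genes gave 1 riser of 31, CYCS at 0.40 (1 and 0 adjusted over the list alone; camera adjusted p = 0.359 unpaired and 0.312 paired). Mitochondrially encoded genes were higher by a median of 0.10, with 3 of 13 rising, among them MT-ATP8 (0.30) and MT-ND2 (0.20), and 5 adjusted over the list alone. That list passed unpaired (adjusted p = 0.0281), and not paired (0.0528) or with an estimated correlation (adjusted p = 0.562), and its median was 0.14 higher in replicate 1. It did not pass without TGF-β replicate 2 (adjusted p = 0.106) or 3 (0.166) or CXCL10 replicate 3 (0.116), with medians of 0.06, 0.06 and 0.09. The 31 cytosolic ribosomal protein genes had a median of -0.06 with 0 single calls, also adjusted over the list alone. They passed in the unpaired fit (adjusted p = 0.0483), and not paired (0.0887) or with an estimated correlation (adjusted p = 0.583). Leaving out TGF-β replicate 1 or 2 or any CXCL10 library also ended that call, with adjusted p values from 0.0632 to 0.296 and medians from -0.07 to -0.05. Of 5 tested histone genes H4C14 rose (1.25), also adjusted over the list alone, and the list did not pass (adjusted p = 0.834 unpaired and 0.829 paired), with a median of -0.14 beside a mean of 0.16 in the unpaired fit.

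Among 2377 annotation terms, 22 passed camera without the pairing, 21 upward and 1 downward, and 21 passed with it, but none passed with an estimated correlation (unpaired adjusted p = 0.914). The strongest were those of ribosome assembly. The large-subunit preribosome (22 genes) had a median log2 change of 0.23 (medians of terms are unpaired), with 10 genes rising and 0 falling in the paired fit. Ribosome biogenesis (98 genes) had a median of 0.18, with 28 rising and 1 falling, and the small-subunit processome (37 genes) one of 0.22, with 15 rising and 0 falling. The term rRNA processing (155 genes) followed at 0.14, and the KEGG term for ribosome biogenesis (72 genes) at 0.17. Their camera adjusted p values ran from 7.63e-05 to 0.00327 without the pairing. The downward term was the cytosolic ribosome (75 genes, median -0.08, adjusted p = 0.0442; 0.0900 paired). The number past the threshold was 46 without TGF-β replicate 1, 9 without TGF-β replicate 2 and 13 without CXCL10 replicate 1.

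The libraries had markers of fibroblasts and also abundant epithelial keratins. Of 15 fibroblast markers 13 reached 1 CPM and 8 reached 100 CPM, and in the paired fit 3 rose and 4 fell of 14 tested (3 and 5 adjusted over the list alone; camera adjusted p = 0.580 unpaired and 0.679 paired), with VIM (0.38) and THY1 (0.43) higher and LUM (-0.32) and DCN (-0.25) lower. Of 15 macrophage markers 4 reached 1 CPM, the highest being CD68 at 39.5 CPM, and 0 of 4 tested passed, also adjusted over the list alone. Of 14 T and NK cell markers 2 reached it, and IL7R rose (1.41), also adjusted over the list alone, while CD4 (0.23) did not pass. Of 12 pericyte and mesangial markers 8 reached 1 CPM and 2 reached 100 CPM, the highest being PDGFRB at 434 CPM. Of 8 tested 3 fell, including NOTCH3 (-0.29) and CSPG4 (-0.25), and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.108 unpaired and 0.0528 paired; fry 0.0148 paired). Of 16 epithelial markers 9 reached 1 CPM and 3 reached 100 CPM, the highest being KRT8 at 2026 CPM. Among 9 tested KRT18 (0.23) and KRT19 (0.28) rose and CDH1 (-1.89, from 2.41 ± 1.13 CPM) fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.121 unpaired and 0.312 paired; 0.0276 unpaired without CXCL10 replicate 1). KRT18, KRT8 and PDGFRB were named after their values were seen. Of 6 tested endothelial markers FLT1 (1.07) and ENG (0.17) rose and ERG (-1.59) fell, the same adjusted over the list alone, with a list median of 0.16 beside a mean of -0.05 in the unpaired fit (camera adjusted p = 0.435 unpaired and 0.341 paired). Of 4 tested proximal tubule markers GPX3 (-0.32) and ASS1 (-0.42) fell, and of 4 tested podocyte markers PODXL (1.34) rose and SYNPO (-0.39) fell, with the same counts adjusted over the list alone and a podocyte median of -0.19 beside a mean of 0.05 in the unpaired fit.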

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

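The fits with pairing and another tool, filter or left-out pair, the block of 2 levels, the fit without both libraries numbered 1, the exact test and the robust dispersion were chosen after the data were seen. Without pairing, 0 genes were called in either direction with RLE factors, library totals, limma-voom, no filter, a mean of at least 5 CPM, an adjusted p of 0.01, both FPKM pseudocounts and robust dispersion. DESeq2 called 172 higher and 163 lower (11 and 14 by at least 2-fold), the edgeR exact test on every gene with a count 162 and 154 (39 and 43), and the replicate block 1162 and 962 (87 and 66). A block of 2 levels, replicate 1 against the rest, gave 1316 and 1132 (94 and 76). Leaving out each library in turn gave 0 to 1302 higher and 0 to 1046 lower genes (0 to 163 and 0 to 123 by at least 2-fold), with 0 for each library except TGF-β replicate 1. Without both libraries numbered 1, the numbers were 1432 and 1207 (133 and 110). A count of 0 cannot fall, so the unpaired leave-outs do not show what fewer libraries do, and the cause of the rises was not tested.

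With the replicate block, RLE factors, library totals, limma-voom, no filter and the block of 2 levels stayed within 1.5 times of 1162 and 962. DESeq2 called 684 and 454 (40 lower by at least 2-fold), an adjusted p of 0.01 left 614 and 436 (34 lower by at least 2-fold), and limma-trend on log2(FPKM + 1) gave 369 and 397 (34 and 13). With a mean of at least 5 CPM, 53 and 19 genes passed 2-fold, since low-count genes were removed. Leaving out both libraries of one replicate number gave 539 to 1533 higher and 365 to 1313 lower genes (55 to 140 and 40 to 116 by at least 2-fold). Where the cause is not named it was not tested.

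Of the 11 gene lists and 22 terms past the threshold, 0 and 0 remained with an estimated correlation and 0 and 0 with fry. Leaving out one library moved the terms to between 9 (without TGF-β replicate 2) and 46 (without TGF-β replicate 1), with 13 without CXCL10 replicate 1, and fry with the block called 2 terms. With the block, the TGF-β target, mitochondrial and ribosomal protein lists lost their call, and it changed no other list call. The 8 lists past the threshold in both fits kept their call without any single library. For 154 named genes, 3015 of 3044 alternative values had the direction of the unpaired fit, and none of the 29 others was called under its alternative. The unpaired fit called 0 genes, so it held no call that could be reversed. The genes were also largely chosen by low p or large change in the same counts, so their shared direction is not independent support. Of 305 list values under alternatives, 0 changed direction with a call. Depth limits genes such as CXCR3, for which 3 counts equal 0.192 to 0.234 CPM.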

Other observations

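The 4 gene lists of this paragraph, and the tests of a mislabelled sample, of growth signalling and of mouse RNA, were chosen after the data were seen, and the reading of the growth-signalling test was made stricter after its result. As the lists were chosen from the changes themselves, their members are counted and no test of a list is given. Of 19 feedback regulators and immediate targets of the growth-factor kinase ERK, 15 rose and 1 fell in the paired fit, with a median log2 change of 0.71. CCND1, which encodes cyclin D1, changed by 1.28, SPRY4 by 1.21, ETV4 by 1.25 and DUSP4 by 1.05, and EGR1 went the other way at -1.10. Of 16 FOXO targets 7 fell and 0 rose, with a median of -0.33, including SESN1 (-0.63) and CCNG2 (-0.71), and their median in replicate 1 differed from that in replicates 2 and 3 by -0.27. Of 3 tested metallothioneins MT2A rose by 1.94 (0.54 to 2.74 over the pairs) and MT1E by 1.27, but their groups overlapped, and both were also higher in replicate 1 than in replicates 2 and 3, by 1.77 and 1.65. Of 13 laminins and laminin-binding integrins 4 rose and 3 fell, among them ITGA6 (1.08) and ITGA3 (0.31) upward and LAMA2 (-0.24) downward.

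Replicate 1 of both groups was shifted in the direction of the CXCL10 change. Across 11970 genes, which are not independent replicates, the difference of replicate 1 from replicates 2 and 3 correlated with the treatment difference at 0.552. With replicate 2 or 3 in place of 1 the correlation over all genes was -0.351 and -0.345, which follows in part from the first value because the 3 differences sum to 0. With genes in 5 classes by level, the correlation for replicate 1 was 0.359 in the least abundant class and 0.927 in the most abundant. Among the most abundant genes the shift of replicate 1 and the treatment difference thus had nearly the same pattern. Gene length is argued against as the source, since the median correlation within 5 classes of genes by length was 0.557. The share of mitochondrial counts stays open, as it followed the first principal component over 6 libraries with a Spearman rho of 0.486 (2-sided exact permutation p = 0.356) and a Pearson r of 0.670 (exact permutation p = 0.132; r = 0.670 without the 2 farthest libraries), between the bounds set for and against it. A mislabelled CXCL10-treated sample in place of TGF-β replicate 1 stays open too. Its place was taken on a scale from 0 for the other TGF-β libraries to 1 for CXCL10 replicates 2 and 3. At 217 genes where CXCL10 replicate 1 was not shifted, TGF-β replicate 1 stood at a median of 0.733 (bootstrap range over genes 0.682 to 0.776). This is nearer to the treated level yet short of the bound set for a mislabel. The range resamples genes, which are not independent replicates, and does not measure the spread between libraries. The genes were also chosen by the gap between the same replicates 2 and 3 that set the scale. TGF-β replicate 1 stood at 0.908 over 497 genes where CXCL10 replicate 1 was shifted along the same direction and at 0.892 on the first principal component, but a shift shared by both replicate 1 libraries would raise these values as well. Other values run with the labels. Across genes the pair 1 difference correlated with the mean difference of pairs 2 and 3 at 0.386, beside 0.436 between pairs 2 and 3. With a mean of at least 5 CPM these were 0.570 and 0.626. They do not decide either, since CXCL10 replicate 1 lay farther along the same axis, which would raise the pair 1 values too. A growth-signalling state shared by replicate 1 and the CXCL10 libraries may be another source, as the ERK list was higher in replicate 1 by a median of 0.454, but that list was chosen from the treatment changes and any shift along this axis would raise it, so the test cannot decide.

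A few of the largest changes in the authors' deposited table lie on overlapping or near-identical genes. SLX1B has an authors' log2 ratio of 4.97, with 0 to 2 counts in the TGF-β libraries and 4 to 66 in the CXCL10 libraries. Summed with its near-identical copy SLX1A the log2 difference was 0.16 (SE 0.08), within the bound set beforehand for reads divided between the copies. SLX1A held 241 to 330 counts per library, so a real rise of SLX1B would also have moved the sum little. The sum therefore cannot decide. For the readthrough gene SENP3-EIF4A1, with an authors' log2 ratio of 2.82, the sum with EIF4A1 and SENP3 differed by 0.37 (SE 0.16), which cannot be told apart from a change of EIF4A1 itself, at 0.38 in the authors' table. No biological explanation was tested for either gene.

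Human gene rows under mouse labels are unlikely to come from mouse RNA counted on human gene models. All 8 of 8 listed human genes without a mouse ortholog reached 1 CPM, with 11.7 CPM for ZNF91, 17.7 CPM for TRIM22 and 5.64 CPM for CD58. NOTCH2NLA (18.8 CPM) and ARHGAP11B (2.45 CPM), also listed, are copies of genes that mice do have. Mouse reads could fall on their rows, so the reading rests on the other listed genes. No other source was tested, and whether the label or the table is at fault stays open.

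With 3 libraries against 3 there are 10 splits, and with 3 pairs 4 labellings within pairs, too few for a share under 0.05. In the unpaired fit 1 of the 10 splits, the real one, gave as many as 2449 genes at an unadjusted p under 0.05. The highest other count was 2190, from TGF-β replicate 1 with CXCL10 replicates 1 and 3 against the rest, which points to a structure of the samples along replicate 1. Among the splits that part all 3 pairs, the highest other count was 291. In the paired fit 1 of the 4 labellings, the real one, gave as many as 2124 genes, and the highest other gave 0.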
